A study of Arabidopsis thaliana with 30 samples.

How the data were processed

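Messenger RNA was sequenced from 7-day-old Arabidopsis thaliana seedlings of 5 genotypes, each without heat (control) or after 85 min at 44 °C. There were 3 libraries in each of the 10 groups, 30 libraries in all. Per the labels, plants grew at 22 °C on agar plates, heat was given by immersing sealed plates in a water bath, RNA was extracted with Trizol and libraries followed an Illumina mRNA-seq protocol. Groups and replicate numbers were taken from the labels. The labels do not say that libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

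The deposited table gives 1 value per gene and library for 38088 genes, and its values were read as FPKM (fragments per kilobase of transcript, scaled to library size), as made by the authors. The unit was inferred from the values: they are not whole numbers, and the smallest value above 0 fell with transcript length across 4064 rarely detected genes (Spearman's rho −0.928, across genes, which are not independent replicates). Bowtie is named in the submitters' processing notes without a version. The counter, genome build and annotation are not given in the sources used here. Sums per library ranged from 735524 to 904077 FPKM in the control libraries and from 931940 to 1099790 in the heat libraries, without overlap. From the smallest steps of rarely detected genes, about 20.2 to 24.7 M fragments per library fell in genes of 600 bp or more, and an FPKM of 1 in a gene of 1 kb stood for about 14.3 to 23.4 reads. These depths are estimates, and low values carry counting error of that order. Median-of-ratios factors computed from the table lay between 0.965 and 1.05.

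Some genes that seedlings express highly were listed at 0 in whole groups, such as the Rubisco small subunit gene RBCS1A, at 0 in 7 of 10 groups and at means from 8936 to 13533 FPKM in the others. Such zeros may be failed estimates, so genes of this kind are described only as listed at 0 and are not named as changed. Gene identifiers were matched to RefSeq symbols for 37792 of the 38088 genes (99.2%). In the name column of the table, 23 gene names had turned into numbers and 1 into a reference error, so identifiers were used instead. Coordinates are those of the RefSeq annotation of the TAIR10.1 assembly, which may not be the build the authors used.

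Values were transformed as log2(FPKM + 1), and genes with at least 1 FPKM in at least 3 libraries were kept (21531 genes). The linear models of limma 3.58.1 in R 4.3.3 were fitted to the 30 libraries with 1 mean per group, with an intensity trend in the empirical Bayes step and Benjamini-Hochberg adjustment per comparison. Genes with an adjusted p under 0.05 were called. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and all adjusted p-values of genes are limma's. Comparisons were the heat effect in each genotype, each other genotype against Col-0 at control and after heat, the difference of each other genotype's heat effect from that of Col-0 (the interaction), and ski2 dcl4 dcl2 against ski2 dcl4. The plan had named a count-based test for the case of count data. It was not run, because the values are FPKM.

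Gene lists fixed beforehand covered the mutated genes, small heat shock proteins, large chaperones, heat shock factors, HSFA2 and heat memory targets, reactive oxygen scavenging, protein folding in the endoplasmic reticulum, anthocyanin and flavonoid synthesis, photosynthesis, cell cycle, elongation growth, phloem, xylem and root markers, starch and sugar metabolism, strigolactone and karrikin signalling, abscisic acid (ABA) and drought, salicylate and defence, nitrate assimilation, RNA silencing and decay, and ONSEN retroelements. Each list was tested with limma's camera at its preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. Of 399 tests of a list in a comparison, 131 passed at the preset correlation and 10 with an estimated one. Below, camera p-values are adjusted.

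The genes named were chosen by a rule. The mutated genes and HSFA2 were always named. In the heat effect in Col-0 and in each other genotype against Col-0, the 6 largest rises and 6 largest falls were named among called genes with a mean of at least 5 FPKM in the higher group and no overlap between the 3 libraries of each group, and from each list the 2 members with the smallest adjusted p. In interactions and in the comparisons that differ by dcl2, the 4 largest rises and falls were named. The text does not describe every gene the rule picks: it leaves out many of those without a name, with near-identical copies that may share reads, or listed at 0. The tests, lists, naming rule and alternatives were fixed before the data were examined, except where stated. The clock genes, the direct comparison of the libraries labelled smxl4 smxl5 with smxl6 smxl7 smxl8, and the further genes named as chosen later were picked after their values were seen.

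The limma steps were tested on simulated data for smxl4 smxl5 against Col-0 at control, over 21531 genes of which 200 were changed. They recovered 80.6% of genes changed 1.5-fold, 91% of those changed 2-fold and 98.5% of those changed 4-fold, with 6 false calls. For the interaction of smxl4 smxl5, where only rises were simulated, the shares were 58.2%, 80.6% and 97%. In both cases the changed genes were drawn from those averaging at least 5 FPKM, on the log scale, in Col-0 control. Noise was drawn independently for each gene and library. Recovery in lower genes, and false calls from deviations of a whole library, were therefore not tested. The alternatives tried were median-of-ratios and upper-quartile rescaling, a pseudocount of 0.1, no filter and a stricter filter, only the libraries of the groups compared, the replicate number as a block, and leaving out each library. Added after seeing the data were robust moderation and a fit without 719 short, organelle or listed-at-0 genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.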

Results

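Transcript levels were measured by mRNA sequencing in 7-day-old Arabidopsis seedlings of 5 genotypes, before and after 85 min at 44 °C, with 3 libraries in each of 10 groups. The genotypes were the wild type Col-0, smxl4 smxl5, smxl6 smxl7 smxl8, ski2 dcl4 and ski2 dcl4 dcl2. SMXL4 and SMXL5 are needed for phloem formation, and SMXL6, SMXL7 and SMXL8 are repressors in strigolactone signalling. SKI2 is an RNA helicase that serves the cytoplasmic exosome, and DCL4 and DCL2 are Dicer-like enzymes that cut double-stranded RNA into small RNAs. The series title names a regulatory loop between SMXL4/5 and the heat shock factor HSFA2 and a trade-off between growth and heat tolerance. Between 23996 and 25857 genes had a value above 0 in each library, and correlations between libraries of a group lay between 0.971 and 0.987. The first principal component held 36.9% of the variance and the second 20.5%.

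The mutated genes were examined first in every group. SMXL5 (AT5G57130, chromosome 5, 23144947 to 23149615) was higher, not lower, in the control libraries labelled smxl4 smxl5, at 15.0 ± 0.42 FPKM (SD, n = 3) against 4.57 ± 0.46 in Col-0 (log2 change 1.53 ± 0.09 SE, adjusted p = 4.95e-11). SMXL4 (AT4G29920, chromosome 4, 14632413 to 14636101) was also higher there, at 3.22 ± 0.32 against 1.93 ± 0.15 (log2 change 0.53, adjusted p = 0.00132). After heat SMXL4 was lower in the libraries labelled smxl4 smxl5, at 1.08 ± 0.25 against 2.22 ± 0.15 (adjusted p = 0.000192), and SMXL5 stood at 3.05 ± 0.24 against 3.12 ± 0.27 (adjusted p = 0.871). These transcript levels go against a plain loss of both transcripts, so directions for this genotype are given for "the libraries labelled smxl4 smxl5"; a gene-level value cannot show where in a gene the reads fell. A lower SMXL4 after heat was not particular to these libraries. In heated ski2 dcl4, SMXL4 stood at 1.21 ± 0.42 FPKM (log2 change −0.56 from Col-0, adjusted p = 0.000432). SMXL5 was also higher than in Col-0 in ski2 dcl4 at control, at 6.3 ± 0.47 FPKM (log2 change 0.39, adjusted p = 0.0014). In smxl6 smxl7 smxl8, SMXL6 was lower at control (3.13 ± 0.19 against 5.44 ± 0.51, adjusted p = 1.05e-05) and after heat (adjusted p = 1.61e-05), and SMXL8 was lower in both (adjusted p = 0.00356 and 0.000363). SMXL7 in that genotype stood at 8.2 ± 0.99 against 8.09 ± 1.11 at control (adjusted p = 0.928) and fell below Col-0 after heat, at 3.19 ± 0.31 against 8.09 ± 0.99 (adjusted p = 1.49e-07). SKI2 was lower in ski2 dcl4 (log2 change −0.77) and in ski2 dcl4 dcl2 (−0.88) at control, and DCL2 was lower in ski2 dcl4 dcl2 (−0.64, adjusted p = 4.59e-06). DCL4 differed from Col-0 by 0.01 in ski2 dcl4 and −0.20 in ski2 dcl4 dcl2 at control on the log2 scale (adjusted p = 0.941 and 0.54). After heat DCL4 was lower in ski2 dcl4, at 2.35 ± 0.19 against 3.26 ± 0.46 FPKM (log2 change −0.34, adjusted p = 0.00353, or 0.0696 with only the libraries of the groups compared), and differed by −0.13 in ski2 dcl4 dcl2 (adjusted p = 0.437).

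**Figure D1:**
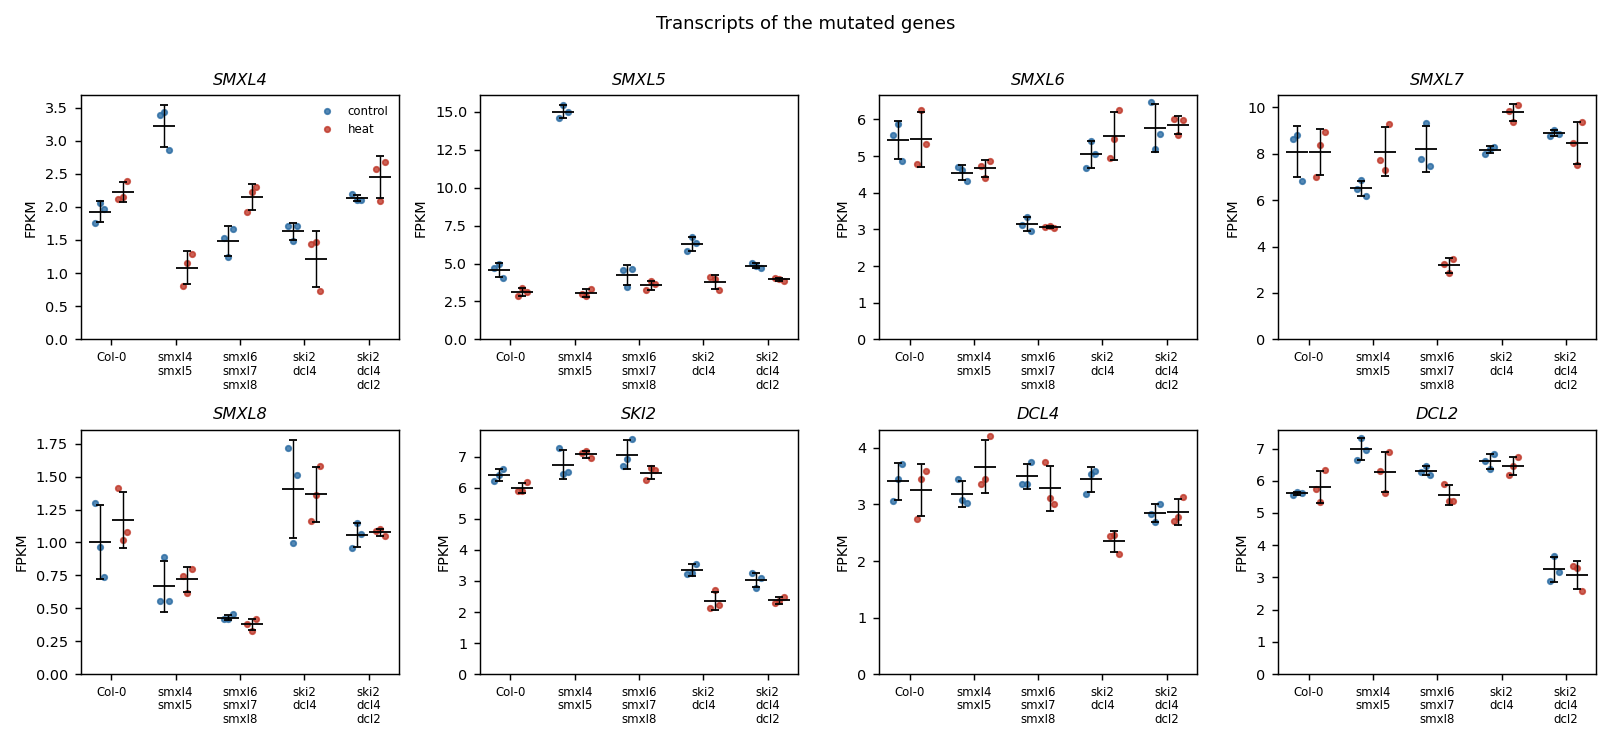
FPKM of the 8 mutated genes (vertical axes) in the 5 genotypes (horizontal axes), control in blue and heat in red; points are libraries, black bars the mean ± SD of 3. SMXL5 stands at 15.0 FPKM in the control libraries labelled smxl4 smxl5, against 4.57 in Col-0.

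Heat in Col-0 raised most heat shock protein genes, and fewer of the heat shock factor genes. HSFA2 (AT2G26150, chromosome 2, 11135624 to 11137792), a heat shock factor that prolongs the heat response, rose from 0.42 ± 0.12 to 352 ± 137 FPKM (log2 change 7.89 ± 0.24 SE, n = 3, adjusted p = 1.51e-17). The small heat shock protein gene HSP17.6A (AT1G59860) rose from 1.56 ± 0.19 to 713 ± 240 FPKM (log2 change 8.08), and its namesake AT5G12030 rose by 7.80. Both belong to a family of similar genes, so reads may have been divided between copies. HSP17.6II rose by 6.87. Of 17 small heat shock protein genes 16 rose and 1 did not pass (16 rose adjusted over the list alone; camera p = 2.47e-12, adjusted p = 0.264 with an estimated correlation). Of 21 large chaperone genes 17 rose and 1 fell (17 and 1 adjusted over the list alone; camera p = 2.06e-06, adjusted p = 0.37 with an estimated correlation). HSP70 (AT3G12580) went from 10.3 ± 1.9 to 406 ± 161 FPKM and HSP90.1 from 6.30 ± 0.66 to 240 ± 123. Of 15 HSFA2 and heat memory targets 12 rose and 3 did not pass (12 rose adjusted over the list alone; camera p = 1.75e-07, adjusted p = 0.264 with an estimated correlation). Among them, MBF1C, a transcriptional coactivator needed for heat tolerance, rose by 5.31 on the log2 scale. The heat shock factors were mixed, with 6 of 19 up, HSFA7A among them (5.02), and 7 down (6 and 7 adjusted over the list alone).

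Other groups also moved with heat in Col-0. Photosynthesis genes rose in 32 of 33 cases (32 adjusted over the list alone; camera p = 2.21e-09, adjusted p = 0.37 with an estimated correlation), with Rubisco activase RCA going from 2976 ± 287 to 5876 ± 849 FPKM. Of 18 starch and sugar genes 9 rose, ADG1 and SUS1 among them (9 adjusted over the list alone; camera p = 0.0438, adjusted p = 0.37 with an estimated correlation). Without Col-0 control replicate 2 or 3, or Col-0 heat replicate 1 or 3, the starch list no longer passed (camera's adjusted p = 0.0523, 0.0536, 0.0805 and 0.0853). Root markers fell in 10 of 14 cases and 1 rose (11 and 1 adjusted over the list alone; camera p = 0.00045, adjusted p = 0.264 with an estimated correlation), and SCR, which patterns the root endodermis, fell by 0.94. Phloem markers fell in 16 of 26 cases and rose in 4 (16 and 4 adjusted over the list alone; camera p = 0.0129, adjusted p = 0.37 with an estimated correlation), with the sugar exporter gene SWEET12 going from 22.1 ± 1.1 to 5.09 ± 0.41 FPKM and the receptor kinase gene BAM3 from 14.6 ± 0.75 to 5.12 ± 0.42. GER3, a germin-like protein gene, fell from 771 ± 61 to 31.9 ± 18.9 FPKM, and the trans-acting siRNA precursor TAS3 from 57.3 ± 2.9 to 1.25 ± 0.55. The remaining lists did not pass camera. Their rises and falls numbered 8 and 1 of 15 for reactive oxygen scavenging, 1 and 6 of 9 for folding in the endoplasmic reticulum, 6 and 7 of 27 for elongation growth, 2 and 2 of 8 for xylem, 1 and 3 of 11 for strigolactone and karrikin, 6 and 1 of 12 for nitrate, and 7 and 7 of 23 for RNA silencing, with these numbers again adjusted over the list alone. They were 4 and 7 of 24 for anthocyanin (3 and 6 adjusted over the list alone), 4 and 7 of 22 for ABA and drought (4 and 5 alone), and 2 and 4 of 15 for salicylate and defence (2 and 3 alone). Of 26 cell cycle genes 7 fell and of 8 mutated genes 1 fell (7 and 1 adjusted over the list alone). The 1 measured ONSEN element did not pass limma's test (0 at an unadjusted p under 0.05). In all, 6437 genes rose and 5880 fell. Upper-quartile rescaling gave 5017 and 7187, with a shift of −0.08 in the median of all genes, so the balance of rises and falls depends on the scaling.

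Heat shock genes rose with heat in each genotype, and 15 of the 17 small heat shock protein genes and 16 of the 21 large chaperone genes rose in all 5. HSFA2 reached 362 ± 79 FPKM in the libraries labelled smxl4 smxl5, 420 ± 123 in smxl6 smxl7 smxl8, 364 ± 35 in ski2 dcl4 and 312 ± 74 in ski2 dcl4 dcl2. Its heat effect differed from that in Col-0 by −0.26, 0.29, −0.24 and −0.30 on the log2 scale (SE 0.34 each; adjusted p = 0.744, 0.648, 0.843 and 0.881), so differences of that size were within the error. Small heat shock protein genes rose in 15 of 17 cases in the libraries labelled smxl4 smxl5 and in 16 of 17 in each other mutant genotype (15, 16, 16 and 17 adjusted over the list alone; camera p = 2.94e-12, 6.52e-15, 7.27e-13 and 3.98e-16, or 0.201, 0.249, 0.239 and 0.133 as adjusted p with an estimated correlation). In total 3843 genes rose and 3191 fell in all 5 genotypes, and log2 changes correlated with those in Col-0 across genes at r = 0.811, 0.786, 0.851 and 0.876 in the order above; genes are not independent replicates. Rises and falls numbered 6438 and 5158 in the libraries labelled smxl4 smxl5, 6182 and 5198 in smxl6 smxl7 smxl8, 6881 and 5084 in ski2 dcl4, and 5551 and 5233 in ski2 dcl4 dcl2. With upper-quartile rescaling the splits were 4481 and 6490, 4568 and 6286, 4774 and 6667, and 4246 and 6261, with median shifts of −0.10, −0.07, −0.12 and −0.07.

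**Figure D2:**
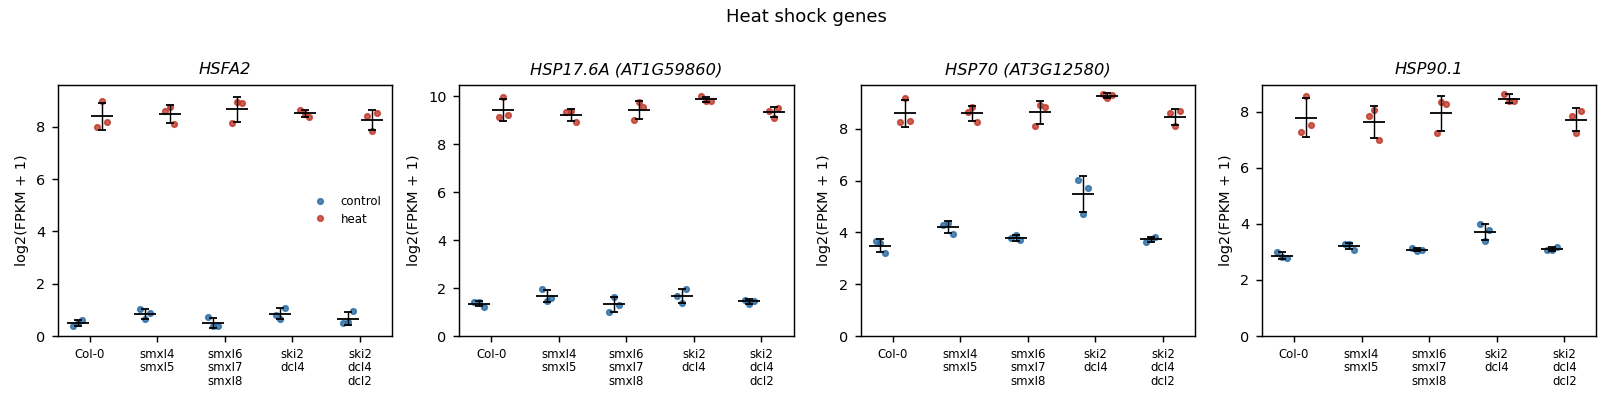
log2(FPKM + 1) of HSFA2, HSP17.6A (AT1G59860), HSP70 (AT3G12580) and HSP90.1 (vertical axes) by genotype (horizontal axes), control in blue and heat in red; points are libraries, black bars the mean ± SD of 3. Each gene is higher after heat in each genotype; HSFA2 rose by 7.89 in Col-0.

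The heat response of some genes differed between another genotype and Col-0. MIOX2, a myo-inositol oxygenase gene, and ASN1, an asparagine synthetase gene induced by low sugar and darkness, rose less with heat in the libraries labelled smxl4 smxl5 and in smxl6 smxl7 smxl8 than in Col-0. MIOX2 went from 33.0 ± 9.2 to 259 ± 136 FPKM in Col-0 and from 101 ± 21 to 138 ± 42 in the libraries labelled smxl4 smxl5 (interaction −2.42, adjusted p = 0.00783), and its interaction was −2.34 in smxl6 smxl7 smxl8 (adjusted p = 0.00644). With only the libraries of the groups compared, neither MIOX2 interaction passed (adjusted p = 0.0552 and 0.0677). The smaller rise was not particular to these genotypes. MIOX2 went from 28.5 ± 14.1 to 59.4 ± 11.2 FPKM in ski2 dcl4 and from 33.6 ± 3.1 to 133 ± 27 in ski2 dcl4 dcl2. ASN1 went from 40.2 ± 6.9 to 260 ± 37 FPKM in Col-0 and from 75.4 ± 17.9 to 110 ± 33 in smxl6 smxl7 smxl8. It went from 36.4 ± 23.9 to 146 ± 29 in ski2 dcl4 and from 50.5 ± 13.2 to 226 ± 41 in ski2 dcl4 dcl2. Its interactions, in the libraries labelled smxl4 smxl5 and in smxl6 smxl7 smxl8, were −2.06 and −2.14 (adjusted p = 0.0192 and 0.0101). The first did not pass without Col-0 control replicate 1, smxl4 smxl5 control replicate 2 or smxl4 smxl5 heat replicate 2 (adjusted p = 0.0641, 0.0559 and 0.0722). In ski2 dcl4, HB-8, a vascular homeodomain gene, fell from 10.6 ± 0.64 to 2.01 ± 0.73 FPKM with heat (interaction −1.60, adjusted p = 3.19e-06). Nitrate assimilation genes as a list moved down in the ski2 dcl4 interaction (camera p = 0.000306, adjusted p = 0.0195 with an estimated correlation), although 0 of 12 members passed limma's test over all genes. At an unadjusted p under 0.05, 1 was positive and 4 negative, and so were 1 and 4 adjusted over the list alone. Over all genes, 156 interactions were positive and 292 negative for smxl4 smxl5, 303 and 837 for smxl6 smxl7 smxl8, 50 and 30 for ski2 dcl4, and 8 and 2 for ski2 dcl4 dcl2. The ski2 dcl4 split was 29 and 37 with upper-quartile rescaling, and 18 were negative without its heat replicate 2. For smxl6 smxl7 smxl8, 196 were positive without Col-0 control replicate 3, and for ski2 dcl4 dcl2, 4 were negative without its heat replicate 3. For smxl4 smxl5, 101 were positive with a pseudocount of 0.1. The totals 448, 1140 and 80 moved by over 1.5 times when single libraries were left out. For the libraries labelled smxl4 smxl5 the total was 152 and 213 without Col-0 control replicates 1 and 2, 263 and 754 without Col-0 heat replicates 1 and 3, 197, 221 and 261 without smxl4 smxl5 control replicates 1, 2 and 3, and 158 without smxl4 smxl5 heat replicate 2. For smxl6 smxl7 smxl8 it was 627 without Col-0 control replicate 2, 393 and 2256 without its control replicates 2 and 3, and 666 and 481 without its heat replicates 1 and 3; without Col-0 control replicate 1 the split was 142 and 536. For ski2 dcl4 it was 51 and 45 without Col-0 control replicates 1 and 2, 52 without Col-0 heat replicate 1, and 48 and 252 without its control replicates 1 and 2, the latter with 90 positive and 162 negative. With only the libraries of the groups compared the totals were 195, 60 and 28, the last with 23 positive and 5 negative, and that of ski2 dcl4 dcl2 was 18 with no filter.

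At control, the libraries labelled smxl4 smxl5 had higher transcripts of IRT1, CYP82C4 and most anthocyanin genes, and lower transcripts of RbcX1, ERF105 and CBF2, than Col-0. IRT1, the root iron transporter gene, stood at 107 ± 9 FPKM against 2.74 ± 1.18 (log2 change 4.89 ± 0.42 SE, n = 3, adjusted p = 1.73e-08), and CYP82C4, an iron-deficiency gene, at 50.8 ± 4.2 against 0.75 ± 0.32. The anthocyanin enzyme gene DFR rose from 7.65 ± 0.71 to 156 ± 39 FPKM, while MYBL2, a repressor of the pathway, fell from 125 ± 27 to 19.1 ± 1.6. Of 24 anthocyanin and flavonoid genes 16 rose and 2 fell (17 and 2 adjusted over the list alone; camera p = 3.33e-07, adjusted p = 0.365 with an estimated correlation). Of 27 elongation growth genes 14 rose and 3 fell, with the gibberellin synthesis gene GA20OX1 higher by 1.42 on the log2 scale and the cell wall gene XTH4 at 658 ± 41 against 267 ± 21 FPKM (15 and 3 adjusted over the list alone; camera p = 0.000453, adjusted p = 0.365 with an estimated correlation). Photosynthesis genes fell in 17 of 33 cases and rose in 3, among them RBCS1B, which has near-identical copies that may share its reads (19 and 3 adjusted over the list alone; camera p = 0.00336, adjusted p = 0.661 with an estimated correlation). RbcX1, a Rubisco assembly chaperone gene, stood at 4.65 ± 0.81 against 102 ± 7 FPKM, and the log2 changes of ERF105 and the cold regulator gene CBF2 were −3.74 and −3.47. Phloem markers fell in 9 of 26 cases and rose in 4, SWEET12 being higher at 44.2 ± 1.6 FPKM against 22.1 ± 1.1 (10 and 5 adjusted over the list alone; camera p = 0.0176, adjusted p = 0.365 with an estimated correlation). Of 15 salicylate and defence genes 7 fell and 1 rose, WRKY70 changing by −2.97 (7 and 1 adjusted over the list alone; camera p = 0.0072, adjusted p = 0.365 with an estimated correlation). In all 3284 genes were higher and 3192 lower.

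Circadian clock genes, chosen after their values were seen, moved with this genotype and with smxl6 smxl7 smxl8. The morning gene LHY stood at 19.2 ± 0.5 FPKM in the control libraries labelled smxl4 smxl5 and at 7.79 ± 0.56 in smxl6 smxl7 smxl8, against 1.02 ± 0.11 in Col-0. The evening gene PRR5 stood at 3.08 ± 0.11 and 4.52 ± 0.28, against 31.7 ± 3.5, and FKF1 at 0.40 ± 0.14 and 0.29 ± 0.08, against 4.67 ± 0.75. All 3 morning genes examined were higher and all 8 evening genes lower in both genotypes, at control and after heat. Other morning genes went both ways. In a separate list of 11, at control, 3 rose and 4 fell in the libraries labelled smxl4 smxl5, and 4 rose and 4 fell in smxl6 smxl7 smxl8. After heat 4 rose and 2 fell in the former, and 1 rose and 2 fell in the latter. Of 5 other evening genes 4 fell in each genotype at control, and 4 and 3 after heat, and 0 rose by limma's test (0 at an unadjusted p under 0.05). With only the libraries of the groups compared, 8 of the 11 did not pass after heat in the libraries labelled smxl4 smxl5 (adjusted p from 0.0586 to 0.157), nor did 10 of the 11 in smxl6 smxl7 smxl8 (0.0595 to 0.323). In smxl6 smxl7 smxl8 after heat, CCA1 and ELF4 did not pass without Col-0 heat replicate 1 (adjusted p = 0.121 and 0.221) or 3 (0.104 and 0.119), nor without its own heat replicate 1 (0.163 and 0.0535) or 3 (0.0741 and 0.0658). ELF4 did not pass there without its own heat replicate 2 (0.0562), nor BOA without Col-0 heat replicate 1 or 3 (0.0809 and 0.0737). GRP7 did not pass there without Col-0 heat replicate 1 or 3 (0.218 and 0.168) or its own heat replicate 1, 2 or 3 (0.0956, 0.0511 and 0.0728). Without Col-0 heat replicate 2 the ELF4 and GRP7 changes there were −1.74 and −1.18, against −1.03 and −0.72 with it included. In ski2 dcl4 dcl2 at control 0 of the 11 genes passed limma's test (0 at an unadjusted p under 0.05), and in ski2 dcl4 at control 2 morning genes rose and 0 evening genes passed (0 unadjusted). After heat, 2 morning and 4 of 8 evening genes were higher in ski2 dcl4, the evening ones being TOC1, ELF4, FKF1 and GRP7 (log2 changes 0.50, 1.12, 0.90 and 0.71). Without Col-0 heat replicate 2 these changes were 0.26, 0.41, 0.47 and 0.24, and GRP7 did not pass (adjusted p = 0.243), nor did it without ski2 dcl4 heat replicate 1 or 2 (0.0607 and 0.0602). These 4 evening genes did not pass with only the libraries of the groups compared (0.129 to 0.235). In ski2 dcl4 dcl2 after heat, TOC1 alone was higher (0.45, adjusted p = 0.0332), with 5 evening genes higher at an unadjusted p under 0.05. TOC1 did not pass without Col-0 heat replicate 2 (change 0.22, adjusted p = 0.225) or its own heat replicate 1, 2 or 3 (0.0982, 0.0675 and 0.102). Nor did it pass with only the libraries of these groups (0.33). The wild-type library Col-0 heat replicate 2 stood apart: PRR5 was at 5.55 FPKM there against 27.5 and 26.1 in the other Col-0 heat libraries, FKF1 at 0.85 against 3.91 and 3.33, and LHY at 4.61 against 0.99 and 1.15. Without that library 8130 genes were called after heat in the libraries labelled smxl4 smxl5 and 5786 in smxl6 smxl7 smxl8, against 7819 and 5128 with it. The gene groups described for the libraries labelled smxl4 smxl5 and for smxl6 smxl7 smxl8 come from libraries whose clock genes also differed from Col-0.

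**Figure D3:**
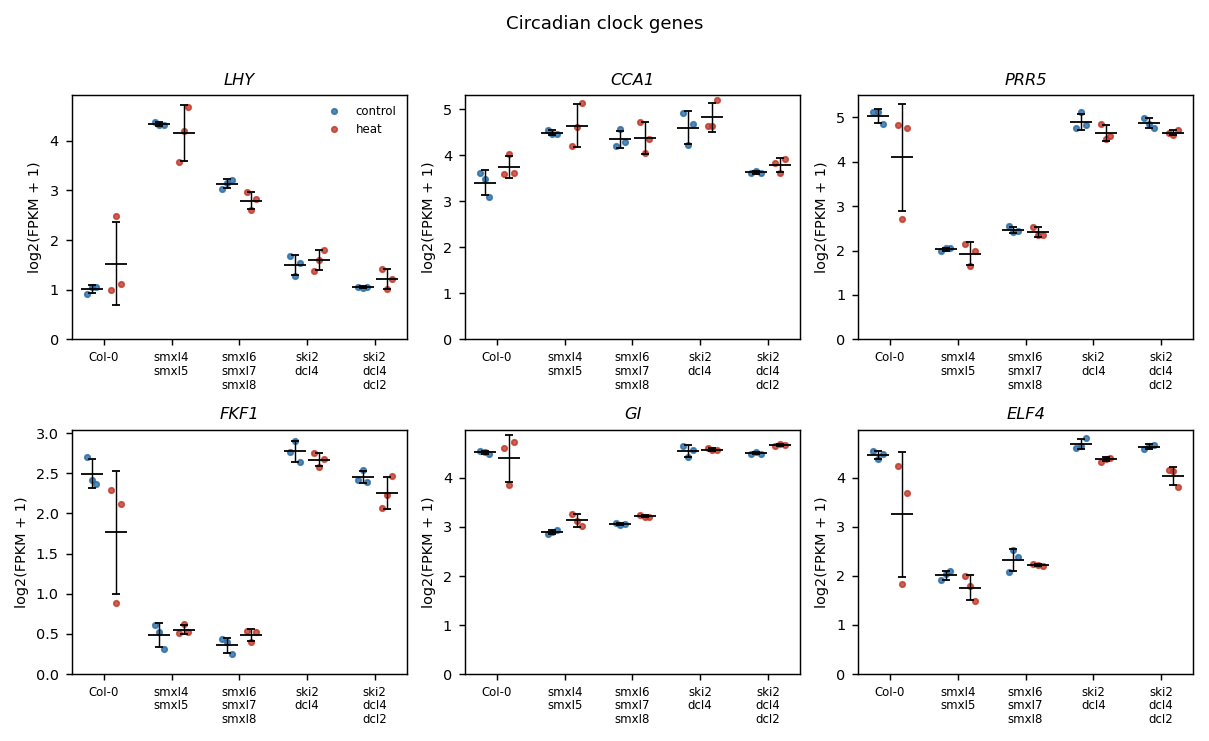
log2(FPKM + 1) of 2 morning genes (LHY, CCA1) and 4 evening genes (PRR5, FKF1, GI, ELF4) on the vertical axes by genotype on the horizontal axes, control in blue and heat in red; points are libraries, black bars the mean ± SD of 3. Evening genes are lower in the libraries labelled smxl4 smxl5 and in smxl6 smxl7 smxl8, with PRR5 at 3.08 and 4.52 FPKM at control against 31.7 in Col-0, and 1 Col-0 heat library lies near them.

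After heat the libraries labelled smxl4 smxl5 differed from heated Col-0 in anthocyanin, chaperone, photosynthesis and phloem genes, in libraries that also had the clock gene differences. Anthocyanin genes were higher in 18 of 24 cases and lower in 1 (19 and 1 adjusted over the list alone; camera p = 8.45e-10, adjusted p = 0.532 with an estimated correlation), with chalcone synthase TT4 at 490 ± 147 against 115 ± 42 FPKM. Large chaperones were higher in 9 of 21 cases (9 adjusted over the list alone; camera p = 0.00263, adjusted p = 0.734 with an estimated correlation), the plastid chaperone gene cpHsc70-2 among them at 270 ± 31 against 98.6 ± 18.1 FPKM. At control 7 of the 21 were already higher and 0 lower by limma's test (8 adjusted over the list alone; camera p = 0.00276, adjusted p = 0.568 with an estimated correlation). At an unadjusted p under 0.05 there were 8 and 0. In the interaction 0 of the 21 passed limma's test, over all genes or adjusted over the list alone, and 3 were positive and 0 negative at an unadjusted p under 0.05. Camera's adjusted p there was 0.587, or 0.0185 without Col-0 heat replicate 2. Of 17 small heat shock protein genes 2 were higher (2 adjusted over the list alone; camera's adjusted p = 0.667, or 0.0389 without Col-0 heat replicate 2). Photosynthesis genes were lower in 20 of 33 cases and higher in 2 (22 and 2 adjusted over the list alone; camera p = 0.000542, adjusted p = 0.734 with an estimated correlation). Phloem markers were lower in 10 of 26 cases and higher in 3 (10 and 3 adjusted over the list alone; camera p = 0.0173, adjusted p = 0.697 with an estimated correlation), and the phloem proton pump gene HA3 stood at 10.1 ± 1.4 against 27.8 ± 0.6 FPKM. Mitochondrial transcripts summed to 2050 ± 233 FPKM in these libraries against 1063 ± 211 in heated Col-0. Of 81 mitochondrial genes 59 were higher and 1 lower, and in the interaction 22 were positive, or 14 without smxl4 smxl5 heat replicate 2. The sugar transporter gene STP1 changed by −3.13 on the log2 scale, and the iron reductase gene FRO2 by 3.66. In all 4120 genes were higher and 3699 lower. A fit with only the libraries of these groups called 3436.

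The smxl6 smxl7 smxl8 seedlings had higher BRC1, a transcription factor gene that restrains branch outgrowth, at 8.48 ± 1.14 FPKM against 0.15 ± 0.03 at control (log2 change 3.04 ± 0.12 SE, n = 3, adjusted p = 1.47e-14) and 5.69 ± 1.45 against 0.20 ± 0.08 after heat. CYP82C4 and IRT1 were also higher at control (4.04 and 3.83), and RbcX1, ERF105 and CBF2 lower (−3.83, −3.28 and −3.21), in libraries that also had the clock gene differences. The starch degradation gene SEX1 stood at 25.5 ± 3.5 against 90.0 ± 6.9 FPKM. Xylem markers fell in 5 of 8 cases at control (8 adjusted over the list alone; camera p = 0.00221, adjusted p = 0.165 with an estimated correlation) and in 5 of 8 after heat (8 adjusted over the list alone; camera p = 7.94e-05, adjusted p = 0.0473 with an estimated correlation), the cellulose synthase gene CESA4 among the latter. Cell cycle genes fell in 7 of 26 cases at control (13 adjusted over the list alone; camera p = 0.000224, adjusted p = 0.703 with an estimated correlation, and 0.0782 without its control replicate 2). Of 12 nitrate genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera p = 0.0334, adjusted p = 0.326 with an estimated correlation); without Col-0 control replicate 2 or 3 or its control replicate 1, that list's camera p was 0.0586, 0.0603 and 0.0905. After heat, anthocyanin genes were higher in 16 of 24 cases and lower in 1 (19 and 1 adjusted over the list alone; camera p = 1.08e-06, adjusted p = 0.646 with an estimated correlation), and photosynthesis genes lower in 24 of 33 and higher in 1 (26 and 1 adjusted over the list alone; camera p = 4.89e-09, adjusted p = 0.646 with an estimated correlation). In all 2891 genes were higher and 2834 lower at control, and 2518 and 2610 after heat. With only the libraries of these groups the totals were 2914 at control and 1767 after heat. Without Col-0 heat replicate 1 or smxl6 smxl7 smxl8 heat replicate 3 the heat total was 2938 or 3202.

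Differences from Col-0 overlapped between the libraries labelled smxl4 smxl5 and smxl6 smxl7 smxl8. At control 1482 genes were higher in both and 1642 lower in both, where independent lists would share 440.9 and 420.1, and log2 changes correlated across genes at r = 0.658. Unchanged groups simulated around the Col-0 mean, with the simulated Col-0 libraries shared, gave r = 0.5. Real changes enlarge the variances, so this r is not on the scale of the real ones. The covariance was 0.131 against a simulated 0.0241. The 3 Col-0 libraries are too few to be split, so part of the overlap may come from them. With ski2 dcl4 dcl2 as the reference of smxl6 smxl7 smxl8 instead, a comparison added after seeing the data, r was 0.451 at control and 0.399 after heat. The libraries labelled smxl4 smxl5 and smxl6 smxl7 smxl8 also shared the clock gene differences from Col-0, which may add to the overlap. Evening genes of ski2 dcl4 dcl2 stood near Col-0 at control (median log2 change −0.021). The change of reference therefore does not remove those shared differences. The libraries labelled smxl4 smxl5 and ski2 dcl4 correlated at r = 0.149 at control, with a covariance of 0.0377 against a simulated 0.0241. They shared 623 rises and 611 falls, against 530.2 and 547 for independent lists, and 1170 genes moved in opposite directions, against 1078.1. With ski2 dcl4 dcl2 as the reference of ski2 dcl4 instead, also added after seeing the data, r was 0.047 at control and 0.079 after heat. The control covariance was then 0.01035. That reference also carries the ski2 and dcl4 mutations, so it removes changes that it shares with ski2 dcl4 as well. For smxl6 smxl7 smxl8 and ski2 dcl4 at control r was 0.156, with a covariance of 0.0341 against 0.0241. They shared 715 rises and 857 falls, against 466.7 and 485.7 for independent lists, and 701 genes moved in opposite directions, against 953. After heat the opposite moves numbered 1656 against 1534.8 for the first of these pairs and 698 against 1015.8 for the second.

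The ski2 dcl4 seedlings had raised ABA and drought genes, which encode mainly protective proteins of seeds and dry tissue. LEA7 stood at 552 ± 114 FPKM against 1.81 ± 0.46 in Col-0 at control (log2 change 7.61 ± 0.41 SE, n = 3, adjusted p = 3.96e-12), RAB18 (AT5G66400) at 1464 ± 323 against 17.2 ± 3.6, and LTI65 at 202 ± 56 against 0.83 ± 0.27. ABR and the lipid transfer protein gene LTP4 were higher by 7.58 and 7.47. All 22 ABA and drought genes rose, at control (22 adjusted over the list alone; camera p = 5.48e-19, adjusted p = 0.0283 with an estimated correlation) and after heat (22 adjusted over the list alone; camera p = 1.18e-17, adjusted p = 0.0376 with an estimated correlation). HSFA6A, a heat shock factor gene induced by ABA, rose from 0.78 ± 0.41 to 53.3 ± 21.3 FPKM at control. Xylem markers fell in 7 of 8 cases at control (7 adjusted over the list alone; camera p = 1.39e-05, adjusted p = 0.0268 with an estimated correlation) and in 7 of 8 after heat (7 adjusted over the list alone; adjusted p = 0.0118 with an estimated correlation), XCP1 and IRX1 among those at control. Cell cycle genes fell in 21 of 26 cases at control (24 adjusted over the list alone; camera p = 1.6e-08, adjusted p = 0.46 with an estimated correlation), and photosynthesis genes in 24 of 33 with 1 up (27 and 1 adjusted over the list alone; camera p = 3.19e-08, adjusted p = 0.484 with an estimated correlation). The photosynthesis list includes RBCS1A, listed at 0 in the Col-0 control libraries and at 7949.1 FPKM or more in those of ski2 dcl4. That 0 may be a failed estimate, so the 1 photosynthesis gene counted as up may not be a real change. The replication clamp gene PCNA1 stood at 12.4 ± 3.8 against 23.3 ± 2.1 FPKM. Of 15 HSFA2 and heat memory targets 8 rose at control, APX2 and HSA32 among them (9 adjusted over the list alone; camera p = 0.000567, adjusted p = 0.448 with an estimated correlation). The nitrate reductase gene NIA2 stood at 200 ± 17 against 360 ± 20 FPKM at control and at 200 ± 49 against 624 ± 132 after heat, where NIA1 was also lower (−1.58, adjusted p = 4.1e-07). In all 3476 genes were higher and 3690 lower at control, and 4798 and 3713 after heat; with only the libraries of these groups the heat total was 5318.

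**Figure D4:**
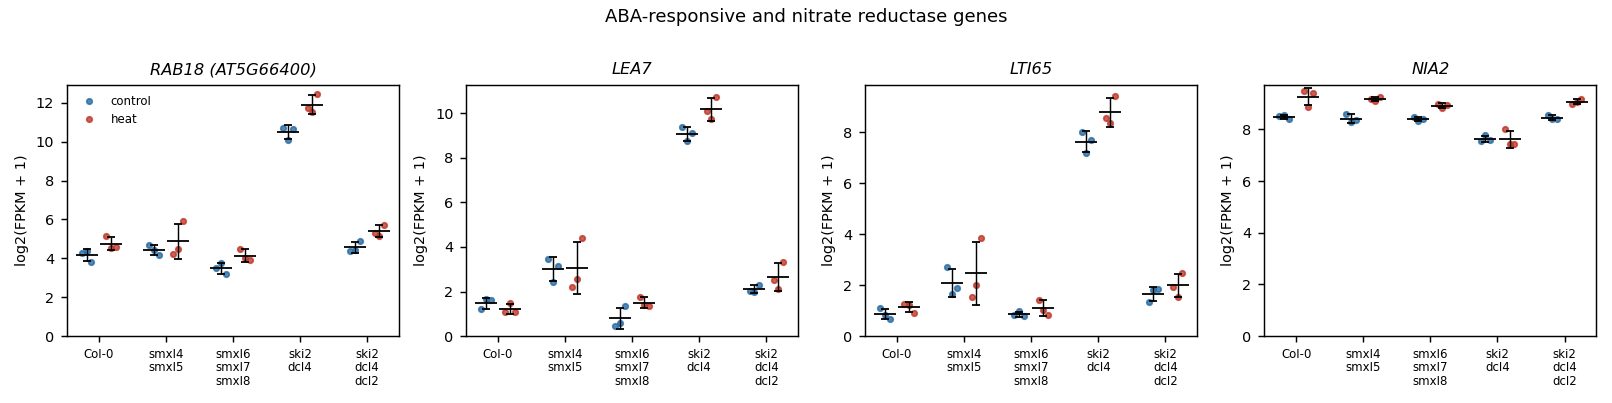
log2(FPKM + 1) of RAB18 (AT5G66400), LEA7, LTI65 and the nitrate reductase gene NIA2 (vertical axes) by genotype (horizontal axes), control in blue and heat in red; points are libraries, black bars the mean ± SD of 3. In ski2 dcl4, LEA7 is at 552 FPKM at control against 1.81 in Col-0, and in ski2 dcl4 dcl2 at 3.30.

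With DCL2 also mutated, ABA and drought genes stood below their level in ski2 dcl4. In ski2 dcl4 dcl2 at control LEA7 stood at 3.30 ± 0.55 FPKM and ABR at 9.30 ± 2.27. The log2 changes of LEA7, ABR and LTI65 from ski2 dcl4 were −6.99, −7.09 and −5.96, and LEA7 differed from Col-0 by 0.62 (adjusted p = 0.82). Against ski2 dcl4, 21 of 22 ABA and drought genes fell at control (22 adjusted over the list alone; camera p = 2.2e-21, adjusted p = 0.0173 with an estimated correlation) and 22 of 22 after heat (22 adjusted over the list alone; adjusted p = 0.0404 with an estimated correlation). Xylem markers rose in 6 of 8 cases at control (7 adjusted over the list alone; camera p = 9.71e-07, adjusted p = 0.0102 with an estimated correlation), and cell cycle genes in 19 of 26 (23 adjusted over the list alone; camera p = 5.17e-08, adjusted p = 0.326 with an estimated correlation). NIA2 was higher than in ski2 dcl4 by 0.82 at control and 1.45 after heat. The 3476 genes higher in ski2 dcl4 than in Col-0 at control had a median log2 change of 0.50 there and of 0.09 in ski2 dcl4 dcl2 against Col-0, and the 3690 lower ones had −0.46 and −0.08. The genes were chosen on the ski2 dcl4 values, which enlarges the first median of each pair, and both comparisons share the Col-0 libraries. In all 3277 genes were higher and 2415 lower in ski2 dcl4 dcl2 than in ski2 dcl4 at control, a total of 3713 without ski2 dcl4 control replicate 1. After heat 3369 were higher and 4555 lower, or 4064 and 3660 with upper-quartile rescaling.

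Against Col-0 at control, ski2 dcl4 dcl2 had lower SKI2 and DCL2 and higher AT2G03965. AT2G03965 (chromosome 2, 1251510 to 1252989) stood at 31.4 ± 0.8 FPKM against 0.01 ± 0.02. AT1G27565 (chromosome 1, 9574550 to 9575189) stood at 35.3 ± 2.1 FPKM at control and was listed at 0 in Col-0. That 0 may be a failed estimate, so AT1G27565 is not named as changed. The orphan gene QQS, known to affect starch content, stood at 72.7 ± 1.9 against 2.08 ± 0.29 FPKM after heat. Of the ABA, cell cycle, anthocyanin, elongation, phloem and xylem lists 0 members passed limma's test at control, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 5 anthocyanin genes rose and 1 fell, 1 elongation, 2 phloem and 1 xylem gene rose, and 0 of the ABA and cell cycle genes passed. The 1 of 33 photosynthesis genes that passed was RBCS1A, which is listed at 0 in Col-0. In all 321 genes were higher and 37 lower at control, and 634 and 642 after heat, or 736 and 446 with median-of-ratios and 711 and 405 with upper-quartile rescaling. The control total was 705 with no filter and 159 with the strict filter. The 37 falls at control were 20 without Col-0 control replicate 1, and 21 and 18 without ski2 dcl4 dcl2 control replicates 1 and 3. The 634 rises after heat were 1017 with no filter and 381 with the strict filter, and the 642 falls were 179 without Col-0 heat replicate 2 and 190, 417 and 345 without ski2 dcl4 dcl2 heat replicates 1, 2 and 3. The 634 rises were 400 without ski2 dcl4 dcl2 heat replicate 1. The heat total was 294 with only the libraries of these groups (248 rises and 46 falls), and 617, 590 and 791 without Col-0 heat replicate 2, ski2 dcl4 dcl2 heat replicate 1 or ski2 dcl4 dcl2 heat replicate 3.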

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

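The tests of explanations in this part were chosen, and the outcomes that would count for or against them written down, only after the results were seen; the splits of the libraries were a planned test, but their expected outcomes were also written down after the counts were known.

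The morning genes CCA1, LHY and RVE8 were higher than in Col-0, and 8 evening genes lower, in the libraries labelled smxl4 smxl5 and in smxl6 smxl7 smxl8; these 11 genes were chosen after their values were seen. The authors' scaling of whole libraries is argued against, since under median-of-ratios and upper-quartile rescaling all 44 results of these genes kept their call and sign, and the largest shift of a log2 change was 0.047, where the smallest change was 0.54. If seedlings had been collected at another time of day, a separate list of rhythmic genes should show a gap of over 0.5 between its morning and evening medians; the smallest gap was 0.42, between the bounds set for and against, and at control the evening medians were −0.64 and −0.665, but the 11 morning genes went both ways (3 higher and 4 lower, 4 and 4) with medians of −0.225 and −0.193, so that test left the explanation open. An effect of the mutations on the clock may also account for the shift: the evening median in ski2 dcl4 dcl2 at control was −0.021, but genotype and collection cannot be told apart, since the labels used here give no time of collection. Replicate 2 of heated Col-0 carries part of the same shift and is labelled wild type, and 1 library does not decide between these explanations.

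SMXL5 was higher in the control libraries labelled smxl4 smxl5 than in any other genotype's. The clock difference argues little for it, since smxl6 smxl7 smxl8 shares that difference and its SMXL5 differed from Col-0 by −0.10 at control. Libraries of another genotype of this series under this label would stay within its range, but the highest other control library held 6.74 FPKM, and the lowest of these 3 held 14.6. Reads from part of a disrupted gene could give a rise of 1.53 on the log2 scale, but 1 value per gene cannot show it, so this stays open, as does a biological rise of the mutated transcript, which was not tested.

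Mitochondrial transcripts, which the comparisons do not use as a group, had a median sum of 1173.1 FPKM in the heat libraries and of 15.0 in the control libraries, a ratio of 78.2. A few genes carried much of the sum. In heated Col-0, with a mean sum of 1062.6 FPKM, the rRNA genes RRN18 and RRN26 stood at 360 ± 73.5 and 153.1 ± 41.4. Of 81 mitochondrial genes 65 rose and 0 fell with heat in Col-0 by limma's test, with a median log2 change of 1.57. The heat sums differed by genotype, at means of 2050.3 FPKM in the libraries labelled smxl4 smxl5, 1367.7 in smxl6 smxl7 smxl8, 1062.6 in Col-0, 1061.7 in ski2 dcl4 and 896.7 in ski2 dcl4 dcl2. The authors' scaling cannot account for the higher sums after heat, since the median-of-ratios factors of any 2 libraries differed by at most 1.09-fold. DNA or RNA without a poly(A) tail in the heat libraries should raise chloroplast transcripts as well. Their median sum was 706.7 FPKM in the control libraries (103.1 to 1745.3) and 1036.1 in the heat libraries (116.7 to 2813.8), a ratio of 1.47. Chloroplast sums started far higher than mitochondrial ones and varied widely, so an equal added amount would give a much smaller ratio. This test therefore cannot decide, and the explanation stays open. More polyadenylated mitochondrial RNA after heat remains a candidate explanation, as a hypothesis that these files cannot test further.

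Several genes responded to heat differently from Col-0 by the interaction test. In the libraries labelled smxl4 smxl5 the interaction was −1.55 for SMXL5, −1.16 for SMXL4, −2.42 for MIOX2, −2.06 for ASN1, −2.22 for SESA2, −1.99 for XTR6, 1.81 for AT4G06665 and 1.74 for AT1G69140. In smxl6 smxl7 smxl8 it was −1.14 for SMXL7, −2.34 for MIOX2, −2.14 for ASN1, −2.29 for AT4G36850 and 1.88 for AT1G69140. In ski2 dcl4 it was −1.60 for HB-8, −3.25 for AT4G27654, −2.93 for AT4G27652, −1.72 for AT3G50800, 1.70 for AT5G07330, 1.52 for GLYI7 and 1.41 for UMP1B. In ski2 dcl4 dcl2 it was 2.57 for TAS3, 1.77 for ETT, 1.21 for PCNA2, 1.01 for HTT2 and −1.38 for TAS1C. A gene named for 1 genotype may respond alike in another. XTR6 went from 58.2 to 21.6 FPKM with heat in smxl6 smxl7 smxl8, and from 23.8 to 28.9 in Col-0. AT4G36850 went from 72.4 to 61.2 in the libraries labelled smxl4 smxl5, and from 40.3 to 133 in Col-0. PCNA2 went from 13.8 to 17.1 in ski2 dcl4, and from 21.6 to 13.2 in Col-0. HB-8 went from 12.5 to 10.3 in ski2 dcl4 dcl2, and from 11.8 to 8.87 in Col-0. AT1G69140 stood at 0.07 FPKM at control and 0.10 after heat in the libraries labelled smxl4 smxl5, and at 0.04 and 0.18 in smxl6 smxl7 smxl8. Its positive interactions come from a fall in Col-0, from 5.11 to 1.01 FPKM. SESA2 stood at 0.06 and 0.04 FPKM in Col-0. In the control libraries labelled smxl4 smxl5 it was at 13.5 ± 14.6 (SD, n = 3). With a pseudocount of 0.1 the TAS1C interaction was −0.05 (adjusted p = 0.991), and AT1G69140 in the libraries labelled smxl4 smxl5, SESA2, AT5G07330 and GLYI7 were no longer called (0.109, 0.271, 0.274 and 0.135). With no filter AT4G06665 and SESA2 were no longer called (0.0506 and 0.0684), nor was SESA2 with the replicate block (0.0607). Leaving out 1 library ended the calls of some of these genes. In the libraries labelled smxl4 smxl5 this held for AT4G06665 without Col-0 control replicate 1 or 2, Col-0 heat replicate 2, any smxl4 smxl5 control replicate, or smxl4 smxl5 heat replicate 2 or 3 (adjusted p from 0.0607 to 0.0942). It held for AT1G69140 without Col-0 control replicate 1, smxl4 smxl5 control replicate 1 or smxl4 smxl5 heat replicate 2 (0.0505 to 0.0627). SESA2 was no longer called without any 1 Col-0 library, smxl4 smxl5 control replicate 1, or smxl4 smxl5 heat replicate 1 or 2 (0.0525 to 0.124). XTR6 was no longer called without Col-0 control replicate 1 or 2, Col-0 heat replicate 1, smxl4 smxl5 control replicate 1 or 2, or smxl4 smxl5 heat replicate 2 (0.0538 to 0.0629), nor ASN1 without Col-0 control replicate 1, smxl4 smxl5 control replicate 2 or smxl4 smxl5 heat replicate 2 (0.0559 to 0.0722). In ski2 dcl4 the call ended for AT5G07330 without Col-0 control replicate 2 or Col-0 heat replicate 1 (0.052 to 0.06). It ended for AT4G27654 without any 1 Col-0 control library, Col-0 heat replicate 1, ski2 dcl4 control replicate 1 or 3, or ski2 dcl4 heat replicate 1 or 2 (0.0505 to 0.0829). It ended for AT3G50800 without Col-0 control replicate 2, Col-0 heat replicate 1, ski2 dcl4 control replicate 1 or 3, or ski2 dcl4 heat replicate 3 (0.0508 to 0.0857). In ski2 dcl4 dcl2 it ended for PCNA2 without Col-0 control replicate 2 or 3, Col-0 heat replicate 1 or 3, ski2 dcl4 dcl2 control replicate 1 or 3, or any ski2 dcl4 dcl2 heat replicate (0.0526 to 0.0884). With only the libraries of the groups compared, the calls of AT4G06665, AT1G69140, MIOX2, SESA2, XTR6, AT5G07330, GLYI7, AT4G27654, AT4G27652 and AT3G50800 ended (0.0552 to 0.306).

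For the counts of called genes, the libraries of each pair of groups were also split in other ways. For 3 against 3 libraries there are 10 splits and 1, the real one, gave as many genes in each comparison; 10 splits are too few for a share under 0.05. The real count and the highest other were 12317 and 1 for heat in Col-0, 11596 and 1 in the libraries labelled smxl4 smxl5, 11380 and 5 in smxl6 smxl7 smxl8, 11965 and 338 in ski2 dcl4, and 10784 and 3 in ski2 dcl4 dcl2. Against Col-0 at control they were 6476 and 1, 5725 and 1038, 7166 and 285, and 358 and 1 in that order of genotypes, and after heat 7819 and 1112, 5128 and 595, 8511 and 3, and 1276 and 1. For ski2 dcl4 dcl2 against ski2 dcl4 they were 5692 and 158 at control and 7924 and 10 after heat. For the added comparison of the libraries labelled smxl4 smxl5 with smxl6 smxl7 smxl8 they were 3921 and 3 at control and 4789 and 6 after heat. For the interactions 100 splits were drawn. As many genes as the real 448, 1140, 80 and 10 came from 16, 8, 24 and 12 splits, with highest others of 10119, 7634, 10889 and 1335, so chance is not excluded for these counts by this test. The highest of these counts exceed the real ones several times over. A split that keeps genotypes intact in 1 condition and exchanges them in the other would turn the genotype effect into an interaction. Which splits gave the high counts was not examined.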

How the results depend on the processing

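Robust moderation, the fit without 719 short, organelle or listed-at-0 genes, and the direct comparison of the libraries labelled smxl4 smxl5 with smxl6 smxl7 smxl8 were chosen after seeing the data; the other alternatives were planned. Of 10301 alternative values of the 669 named gene results, 123 (of 62 results) had the opposite sign; 0 of these were called by limma, with all libraries (adjusted p of 0.18 or more) or under the alternative (0.224 or more). Rescaling, the pseudocount of 0.1, the replicate block, robust moderation and the fit without those 719 genes moved no total of called genes by over 1.5 times, but moved some rises or falls. Upper-quartile rescaling took falls in ski2 dcl4 dcl2 after heat from 642 to 405 and positive ski2 dcl4 interactions from 50 to 29. The pseudocount took positive interactions of smxl4 smxl5 from 156 to 101, and it and the fit without the 719 genes took negative ones of ski2 dcl4 dcl2 from 2 to 1. Labels share replicate numbers between groups, but same-numbered libraries did not deviate together (mean correlations −0.012, −0.003 and −0.014, against 0.005 for different numbers), and 7 of 30 libraries correlated best with their own number. With the block, 128 list calls passed against 131.

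With only the libraries of the groups compared, 17 of 21 counts were lower and 4 higher: heat in ski2 dcl4 dcl2 (10784 to 11910), the libraries labelled smxl4 smxl5 at control (6476 to 7116), and ski2 dcl4 dcl2 at control (358 to 369) and in the interaction (10 to 14). Counts moved by over 1.5 times were 2914 (smxl6 smxl7 smxl8, control), 3436, 1767, 5318 and 294 (the genotypes after heat, in the order of the report), 195, 60 and 28 (the first 3 interactions) and 1383 (the libraries labelled smxl4 smxl5 against smxl6 smxl7 smxl8 at control). For ski2 dcl4 dcl2 at control the count was 705 with no filter and 159 with the strict filter, and its interaction count was 18 with no filter (6 negative). Its rises after heat went from 634 to 1017 with no filter and 381 with the strict filter, and negative ski2 dcl4 interactions from 30 to 46 with no filter. List calls fell from 131 to 10 with an estimated correlation, and were 131 and 126 under median-of-ratios and upper-quartile rescaling and 118 to 149 when libraries were left out. For these moves the cause was not tested.

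Leaving out 1 library gave 2938 to 5786 genes for smxl6 smxl7 smxl8 after heat, 590 to 1529 for ski2 dcl4 dcl2 after heat and 3713 to 5749 for ski2 dcl4 dcl2 against ski2 dcl4 at control. The interaction of the libraries labelled smxl4 smxl5 gave 152 to 754: 152 and 213 without Col-0 control replicates 1 and 2, 263 and 754 without Col-0 heat replicates 1 and 3, 197, 221 and 261 without smxl4 smxl5 control replicates 1, 2 and 3, and 158 without smxl4 smxl5 heat replicate 2. That of smxl6 smxl7 smxl8 gave 393 to 2256: 627 without Col-0 control replicate 2, 393 and 2256 without its control replicates 2 and 3, 666 and 481 without its heat replicates 1 and 3, and a split of 142 and 536 without Col-0 control replicate 1. That of ski2 dcl4 gave 45 to 252: 51 and 45 without Col-0 control replicates 1 and 2, 52 without Col-0 heat replicate 1, and 48 and 252 without its control replicates 1 and 2. In the interaction of smxl4 smxl5, 58.2% of simulated 1.5-fold differences were recovered, in genes averaging at least 5 FPKM in Col-0 control. Smaller differences, changes in lower genes and the other interactions were not simulated.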

Other observations

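The genes, libraries and tests in this part were chosen after the values were seen, as was the comparison of the libraries labelled smxl4 smxl5 with smxl6 smxl7 smxl8. TAS1C and TAS3 are precursors of trans-acting siRNAs, small RNAs that DCL4 makes, and were not tested as a group. TAS1C stood at 32.7 ± 1.4 FPKM in ski2 dcl4 dcl2 at control, against 7.45 ± 0.72 in Col-0 and 7.02 ± 1.07 in ski2 dcl4 (n = 3). TAS3 stood at 60.4 ± 2.25 in ski2 dcl4 dcl2 and 57.3 ± 2.9 in Col-0 at control (adjusted p = 0.999), and at 12.9 ± 1.8 and 1.25 ± 0.55 after heat. In ski2 dcl4 it was at 31.1 at control and 0.77 after heat. ETT, an auxin response factor gene targeted by TAS3 siRNAs, stood at 14.4 ± 0.6 FPKM at control and 4.32 ± 0.26 after heat in Col-0, at 25.5 ± 0.3 and 30.2 ± 0.5 in ski2 dcl4 dcl2, and at 20.9 ± 1.26 and 18.3 ± 1.26 in ski2 dcl4. HTT2, a target of TAS1 siRNAs, stood at 8.21 and 3.52 in Col-0, at 24.5 and 24.4 in ski2 dcl4 dcl2, and at 23.58 and 23.72 in ski2 dcl4. The ski2 dcl4 interactions were 1.35 for ETT and 1.03 for HTT2 (adjusted p = 3.19e-06 and 0.00328).

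Among the tested genes, loci other than protein-coding genes were over-represented in those higher in ski2 dcl4 dcl2 than in Col-0 at control. They made up 201 of 321 (62.6%), of which 171 had a RefSeq type naming a pseudogene. Among all tested genes they made up 1704 of 21531 (7.91%, Fisher's exact test, two-sided, p = 4.54e-140). Genes are not independent, and the pseudogene types were not divided further. Many of the 321 genes passed the filter through libraries in which they were high. Without RBCS1A, 273 to 295 reached 1 FPKM in the ski2 dcl4 dcl2 control libraries, and 69 to 72 in those of Col-0. Loci that stayed below 1 FPKM in all groups were left out, so the filter partly sets these shares and p-values. In ski2 dcl4 at control, loci other than protein-coding genes made up 326 of 3476 higher genes (9.38%, Fisher's exact test, two-sided, p = 0.000598). Of these 218 had a RefSeq type naming a pseudogene. After heat they made up 228 of 634 higher genes in ski2 dcl4 dcl2 (36.0%; Fisher's exact test, two-sided, p = 1.25e-92) and 360 of 4798 in ski2 dcl4 (7.50%; p = 0.237). Of the 321 genes 272 were also higher in ski2 dcl4, where independent lists would share 51.8. Unchanged groups simulated around the Col-0 mean shared 0. Such groups hold no change to share, so that 0 cannot show what the real Col-0 libraries add. Both comparisons use the same 3 Col-0 libraries, so part of the excess may come from them. They do not account for all of it: of the 321 genes other than RBCS1A, 215 to 221 reached 1 FPKM in the ski2 dcl4 control libraries. In the control libraries of Col-0 69 to 72 did, in those of smxl6 smxl7 smxl8, which neither comparison uses, 72 to 85, and in those labelled smxl4 smxl5 67, 68 and 137. Transcripts of the DNA demethylase gene DML1 and of NRPD1A, a subunit gene of RNA polymerase IV, were lower in this genotype (−0.68 and −0.49, adjusted p = 0.000108 and 8.14e-05) and in ski2 dcl4 (−0.94 and −0.49, adjusted p = 2.64e-07 and 1.82e-05).

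Without RBCS1A, 320 of these 321 genes were compared between the libraries of each group. In the control libraries labelled smxl4 smxl5, replicate 3 exceeded both others in 240 of them, against 29 in each of replicates 1 and 2. Replicate 1 exceeded both others in 224 in ski2 dcl4 heat, 164 in ski2 dcl4 dcl2 control and 153 in Col-0 heat. AT5G32143 stood at 15.9 FPKM in replicate 3 and at 0.09 and 0.18 in the others, and AT1G42040 at 9.01 and listed at 0 in the others. AT1G54420 was listed at 0 in all 3 and lay between 26.2 and 30.8 FPKM in ski2 dcl4 dcl2 control.

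Replicate 2 of heated Col-0, whose clock genes stood apart, held HA3 at 28.4 FPKM, where the other Col-0 heat libraries had 27.5 and 27.5 and the libraries labelled smxl4 smxl5 had 8.69 to 11.4. BRC1 was at 0.13 FPKM in it, and at 4.71 to 7.35 in smxl6 smxl7 smxl8 heat.

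Compared with each other at control, the libraries labelled smxl4 smxl5 had 1810 genes higher and 2111 lower than smxl6 smxl7 smxl8. With only the libraries of these groups 564 were higher and 819 lower. Anthocyanin genes were higher in 16 of 24 cases and lower in 1 (16 and 1 adjusted over the list alone), and phloem markers lower in 9 of 26 and higher in 1 (10 and 3 adjusted over the list alone). After heat 2641 genes were higher and 2148 lower, with phloem markers lower in 11 of 26 cases and higher in 1 (11 and 1 adjusted over the list alone). BRC1 was at 0.03 FPKM in the control libraries labelled smxl4 smxl5.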
